A study of Mus musculus with 9 samples.

How the data were processed

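Nuclei positive for NeuN were sorted from mouse cortex, and RNA was extracted with a kit for formalin-fixed tissue and made into libraries with the SMARTer stranded total RNA kit for pico input, per the labels' protocols. This kit copies total RNA with random priming, so introns and non-coding RNA are read along with messenger RNA. Paired reads of 40 bases on each end were sequenced, per the labels. The deposited values are whole-number counts of read pairs per gene, not normalised, 1 table per library. They were made by featureCounts with whole genes as features, so that exons and introns count together, with read pairs and reversed strand, on Ensembl annotation release 102, per the file headers. The submitters' processing notes name the build GRCm38, STAR 2.7.9a, Subread 2.0.0 and DESeq2 1.36.0, without saying what each was used for. With the default setting, read pairs that overlap several genes on the same strand are left out of the counts, so genes nested in others are counted low or at 0. Genes on opposite strands are told apart by the stranded counting.

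The annotation held 55401 genes, of which 55141 (99.5%) had a symbol in the reference table, and 32394 had a count in some library. Totals ran from 21584712 to 26715938 counts per library. Libraries of the same group differed by more than sampling noise (chi-square per gene 9.03 to 27.0) and their lowest Spearman correlation was 0.990, so no library was a copy of another. Groups were taken from the sample titles.

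Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with at least 10 counts in enough libraries (filterByExpr by group) were kept, 16046 in all, with TMM factors. One quasi-likelihood model with robust dispersion and 3 group means was fitted to the 9 libraries, leaving 6 residual degrees of freedom, with a median prior of 7.15. Each of the 3 comparisons was tested with Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes. Standard errors are the log2 fold change divided by the square root of F, and intervals cover 95%. A gene at 0 in a whole group was compared with a floor of 3 counts over that group, and its fold is then a lower bound. Reads copied by PCR without molecular identifiers are not independent molecules, so such floors cover counting error only. The median standard error of a log2 fold change was 0.14, so a typical gene had a 95% interval of about 0.30 on either side.

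The 36 gene lists, fixed before the data were examined, cover cell types and regions that a cortical sort could hold, synaptic genes, tau and Cdk5, stress, immune, metabolic and chromatin genes. Of 952 listed symbols 948 were in the files and 786 were tested. The 34 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation 0 lists passed in each comparison, and 0 had an unadjusted p under 0.05, while fry in 1 direction called 0, 1 and 1 lists. In no list that passed did the median, the mean and the camera direction differ in sign, while 8, 5 and 9 of the other lists had such a difference for scrambled peptide against wild type, Cdk5i against scrambled peptide and Cdk5i against wild type. Counts adjusted over the list alone apply the edgeR p-values within 1 list.

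The genes named were set before the data were examined, per comparison. They are up to 8 rising and 8 falling genes past the threshold with the largest log2 fold change, a mean count of at least 50 and groups that do not overlap, leaving out predicted genes, pseudogenes and ribosomal or mitochondrial RNA, together with members of the lists and Mapt, Prnp, Cdk5, Cdk5r1 and Cdk5r2. Non-coding RNAs and the pseudogene past the threshold, genes past the threshold in a list alone, Zfp990, the neighbours of Gm9866 and Mob3b, Tnxb, Arc and Fos were chosen after their values were seen. The values of some genes of these lists are not reported here.

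The procedure was tested on simulated data with the means, depths and spread of the real libraries and 200 changed genes, in 5 sets for each comparison, on 16046 genes. In the comparison of the peptides it recovered 38% of genes changed by 0.5 on the log2 scale, 72.4% at 1, 85.6% at 1.5 and 94% at 2. For scrambled peptide against wild type these shares were 32.4, 68, 80.8 and 90%, and for Cdk5i against wild type 40, 70.8, 84.8 and 95.2%. The share of false genes among those called averaged 7.15, 7.72 and 7.30% in the order of the report, above the nominal 5%, and ranged from 3.60 to 12.2% between sets. A further 20 sets without any change gave a mean of 0.75, 1.1 and 0.95 called genes.

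Alternatives set beforehand were DESeq2 1.42.0, limma-voom with sample weights, DESeq2 size factors, library sizes from nuclear genes, no low-count filter, a filter of 50 counts, a fit of only the groups compared, the replicate number as a block, non-robust dispersion, 1 surrogate variable from sva 3.50.0 and leaving out each library in turn. Scores of inhibitory against excitatory markers, of mitochondrially encoded genes and of immediate early genes as covariates, list tests with other scalings, and separate wild-type libraries for the comparisons with wild type were chosen after seeing the data.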

Results

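RNA was sequenced from nuclei carrying NeuN, a marker of neuronal nuclei, that had been sorted from the cortex of mice aged 7 to 9 months. The 9 libraries fell into 3 groups of 3: wild-type mice without treatment, mice carrying a P301S tau transgene that received a scrambled peptide, and mice with the same transgene that received the Cdk5i peptide. P301S is a mutation of the tau gene MAPT that causes inherited frontotemporal dementia. Cdk5 is a neuronal kinase that is activated by p35 and phosphorylates tau, among other proteins. Both peptides were injected into the abdomen on alternate days at 20 mg per kg body weight. Because the wild-type mice received no peptide, genotype and injection cannot be separated in either comparison with wild type. No label states that each library came from a separate animal, so p-values measure the spread between these samples, which may be technical.

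The 3 wild-type libraries held 21704644, 22019590 and 22254046 counts, the scrambled-peptide libraries 24909541, 21584712 and 25367838, and the Cdk5i libraries 23292622, 26715938 and 25433726. Ribosomal RNA genes took 0.771 to 3.06% of the counts and mitochondrially encoded genes 0.0793 to 0.137%. Markers of excitatory cortical neurons summed to 2728 ± 53.9 CPM in wild type, 2745 ± 65.8 with scrambled peptide and 2834 ± 306 with Cdk5i (SD, n = 3), and those of inhibitory neurons to 3430 ± 285, 2952 ± 173 and 3354 ± 147 CPM. Microglial markers summed to 98.3 ± 55.4, 78.7 ± 6.96 and 87.7 ± 41.9 CPM in the same order of groups. Markers of oligodendrocyte precursors summed to 1320 ± 151, 1332 ± 46.1 and 1376 ± 33.9 CPM. Those of astrocytes summed to 851 ± 33.5, 768 ± 115 and 830 ± 111 CPM. Sums of different lists do not give shares of cells. The Y-linked gene Ddx3y was read in 9 of 9 libraries, at 31.0 to 38.6 CPM. The first 3 principal components held 21.4, 17.1 and 14.1% of the variance, and the groups did not form separate clusters on them.

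The first comparison asked how cortical neurons of P301S mice given scrambled peptide differed from those of wild-type mice. Among 16046 genes tested, 6 rose and 7 fell. The gene with the lowest adjusted p lay at the prion protein locus on chromosome 2 (GRCm38). This gene, Lamr1-ps1 (ENSMUSG00000081229, 131904086 to 131904959), a processed pseudogene of the laminin receptor gene, had 0 counts in the wild-type libraries and 50 to 74 in those with scrambled peptide. This was at least 57.6-fold higher against a floor of 3 counts over the wild-type group. Next to it, Prn (ENSMUSG00000098754, 131909957 to 131956130) rose 3.42-fold, from 1.23 ± 0.159 to 4.21 ± 0.337 CPM (SD, n = 3). In one widely used P301S line the mouse prion promoter drives the human tau transgene, but the labels do not name the line.

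Prn is a gene model that overlaps Prnp and Prnd on the same strand, and Prnp itself, the prion protein gene, had 0 to 2 counts per library, so reads of the locus cannot be assigned to 1 gene. Lamr1-ps1 shares sequence with the parent gene it derives from, whose reads could be counted under it. Such reads would be found in wild type too. The 0 counts there, against 50 to 74 with scrambled peptide and 52 to 60 with Cdk5i, argue against the parent gene as their source. Reads of a transgene that carried sequence of this locus would be counted under the same names, so the folds of Prn and Lamr1-ps1 need not be changes of the mouse genes. The long non-coding RNA 4930590L14Rik (chromosome 3, 140951876 to 140953247) also had 0 counts in wild type, against 15 to 20 counts with scrambled peptide, at least 15.1-fold higher. The edgeR quasi-likelihood test gave an adjusted p of 2.95e-04 for Lamr1-ps1, 0.0168 for Prn and 0.0162 for 4930590L14Rik. Ccnd3 (chromosome 17, 47505051 to 47599691), which encodes the G1 cyclin D3, rose 2.18-fold from 2.69 ± 0.397 to 5.85 ± 0.590 CPM (SD, n = 3), with an edgeR adjusted p of 0.0181. Pdzd2, a PDZ domain gene, rose 1.39-fold and the non-coding RNA 2610035D17Rik 1.34-fold, with edgeR adjusted p values of 0.0408 and 0.0336.

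Unc5c (ENSMUSG00000059921, chromosome 3, 141465216 to 141834924), a receptor for the axon guidance factor netrin, fell from 752 ± 45.3 to 482 ± 14.5 CPM (SD, n = 3), a log2 fold change of -0.64 with a standard error of 0.07 and an edgeR adjusted p of 0.00441. The long non-coding RNA Gm9866 (ENSMUSG00000094002, chromosome 12, 27050950 to 27160633) fell from 62.4 ± 2.26 to 35.6 ± 4.36 CPM (SD, n = 3), a log2 fold change of -0.81 ± 0.08 (SE) with an edgeR adjusted p of 0.00142. Also on chromosome 12, the doublecortin domain gene Dcdc2c had a log2 fold change of -1.34 and the non-coding RNA 2410018L13Rik one of -2.06. Zfp951, of the KRAB zinc finger family whose near-identical copies can share reads, fell by 1.08 on the log2 scale, the neuropeptide S receptor gene Npsr1 by 0.64 and the PDZ domain gene Pdzrn4 by 0.42. The edgeR adjusted p values of these 5 genes lay between 0.0336 and 0.0492.

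The mouse tau gene, Mapt, measured 233 ± 10.7 CPM with scrambled peptide and 204 ± 8.81 CPM in wild type (SD, n = 3), a log2 fold change of 0.19 (95% interval 0.06 to 0.33) that did not pass the edgeR test over all genes (adjusted p = 0.330). Counting used the mouse annotation, so RNA of the transgene was not measured as such. These counts do not show whether total tau RNA differed. Cdk5 had a log2 fold change of 0.26 (edgeR adjusted p = 0.477), and Cdk5r1, which encodes the Cdk5 activator p35, one of -0.0036 (interval -0.17 to 0.17). Cdk5r2, the gene of the related activator p39, had 0 counts in 9 of 9 libraries. This does not show that the gene is silent, since read pairs that overlap several genes on the same strand are left out. Overlap at Cdk5r2 was not examined.

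**Figure D1:**
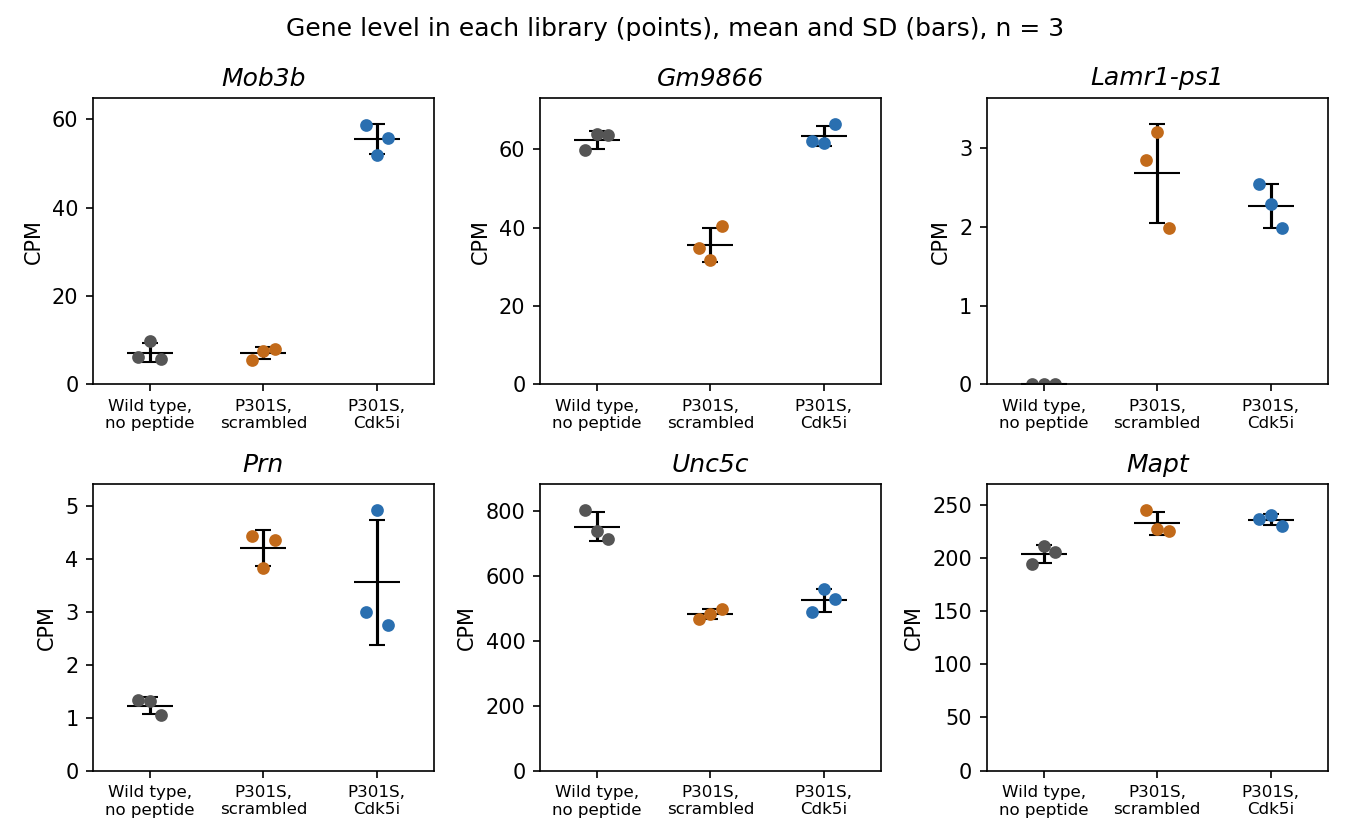
Normalised level in CPM (vertical axes) of 6 genes in each of the 9 libraries, grouped on the horizontal axes, with points for libraries and bars for the mean and SD of 3 libraries. Mob3b averages 55.5 CPM in the Cdk5i libraries and 7.03 CPM in the scrambled-peptide libraries, Gm9866 is lower in the scrambled-peptide libraries, and Lamr1-ps1 is at 0 in wild type.

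Of 34 gene lists tested in this comparison, 1 changed. Oligodendrocyte markers, which trace RNA of the myelin-forming cells rather than of neurons, rose: 12 of 14 measured members had positive fold changes, with a median log2 fold change of 0.30. The list's summed level was 174 ± 4.35 CPM in wild type and 215 ± 14.1 CPM with scrambled peptide (SD, n = 3). No member passed the edgeR test over all genes, while 3 were higher when adjusted over the list alone: the myelin gene Mobp (1.83 ± 0.454 to 3.41 ± 1.02 CPM, SD, n = 3), the galactolipid enzyme gene Ugt8a, with a log2 fold change of 0.59, and Enpp2, with 0.30. Mbp, the myelin basic protein gene, had a log2 fold change of 0.29 and an edgeR adjusted p of 0.736. Camera with a preset correlation gave an adjusted p of 0.00491 for the list. With an estimated correlation the call was lost (adjusted p = 0.953), and without scrambled replicate 1 it was lost as well (camera adjusted p = 0.0522). Over the 15 alternatives the adjusted p of the list ranged from 3.24e-04 to 0.953. The number of lists past the threshold was 2 without wild-type replicate 2, 4 without scrambled replicate 3 and 7 without wild-type replicate 3.

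Synaptic receptor genes did not pass as lists. Of 46 postsynaptic and glutamate receptor genes, 28 had negative fold changes (median log2 fold change -0.06), and of 21 GABA receptor and inhibitory synapse genes 15 did (median -0.11), both with a camera adjusted p of 0.0584. When adjusted over the list alone, 3 genes of each list were lower with scrambled peptide. Among them were the glutamate receptor genes Gria4 (log2 fold change -0.31) and Grik1 (-0.34), the GABA receptor gene Gabra3 (-0.26) and Gphn (-0.44), the scaffold of inhibitory synapses. The same adjustment over the list alone gave Calb1 (-0.35), Hdac9 (-0.35) and the leukocyte gene Ptprc (-1.66) as lower. In fry's test of change in either direction, 3 lists passed: cell cycle genes (fry adjusted p = 0.00169), chromatin modifiers (0.0172) and the GABA list (0.0257).

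Before adjustment, 1614 genes (10.1%) had p under 0.05, and 2613 genes (16.3%) showed no overlap between the groups, against 10% by chance. Groups simulated without change gave at most 3 genes in 20 sets, with a lowest edgeR adjusted p of 4.69e-04, and of the 13 genes Lamr1-ps1 alone lay below it. Genes vary independently in these sets, which therefore lack any structure of the samples. Lamr1-ps1 and Gm9866 passed with each of the 6 libraries left out in turn. The count of 13 fell to 2 without scrambled replicate 2, where the other 11 genes had edgeR adjusted p values of 0.0585 to 0.334. It fell to 3, with Unc5c, without wild-type replicate 2 or 3, the other 10 genes lying at 0.0675 to 0.189 and at 0.0879 to 0.179 by edgeR. Without wild-type replicate 1 the count was 8 and 5 of the 13 passed, with edgeR adjusted p values of 0.0527 to 0.195 for the others. Of the 13, 6 passed without scrambled replicate 1 (0.0736 to 0.173 for the others by edgeR) and 8 without scrambled replicate 3 (0.0597 to 0.112). DESeq2 called 75 genes, 12 of them among the 13, while the count was 6 with non-robust dispersion or a filter of 50 counts and 3 with the score of mitochondrially encoded genes in each library added to the fit, a choice made after the data were seen.

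The second comparison asked what the Cdk5i peptide changed in P301S mice, both groups being injected. There were 2 genes past the threshold, both higher with Cdk5i. Mob3b (ENSMUSG00000073910, chromosome 4, 34949074 to 35157484), of the MOB family of kinase activators, rose 7.91-fold, from 7.03 ± 1.33 to 55.5 ± 3.40 CPM (SD, n = 3), a log2 fold change of 2.98 with a standard error of 0.19. Mob3b was higher in 3 of 3 Cdk5i libraries than in any of the other 6. Its neighbour C9orf72 had a log2 fold change of 0.32 (edgeR adjusted p = 0.493). Gm9866 rose 1.78-fold, from 35.6 ± 4.36 to 63.4 ± 2.60 CPM (SD, n = 3), a level that differed from wild type by 0.02 on the log2 scale (95% interval -0.15 to 0.20). The edgeR adjusted p was 9.83e-04 for both genes, and both passed in 19 of 19 alternative settings.

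Groups simulated without change from the depth and spread of these libraries gave up to 3 genes in 20 sets, with a lowest edgeR adjusted p of 3.20e-04, so neither the count of 2 nor its p exceeded that background. At least 1 gene passed in 13 of the 20 sets. Genes vary independently in these sets, which therefore lack any structure of the samples. The size of the Mob3b fold was not compared with them. Before adjustment 855 genes (5.33%) had p under 0.05, and 1658 (10.3%) had groups that did not overlap, against 10% by chance. DESeq2 called 26 genes. Without scrambled replicate 3 the edgeR count was 18, without scrambled replicate 1 or Cdk5i replicate 1 it was 7, and without Cdk5i replicate 3 it was 6, Mob3b and Gm9866 being among these genes each time. Longer genes had higher fold changes: across 16046 genes, which are not independent replicates, the log2 fold change had a Pearson's r of 0.22 with log2 gene length. This r was -0.13 for scrambled peptide against wild type and 0.07 for Cdk5i against wild type.

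Neither Mapt (log2 fold change 0.02, 95% interval -0.11 to 0.15) nor Cdk5 (-0.19, interval -0.44 to 0.06) nor Cdk5r1 (-0.14, interval -0.30 to 0.03) passed the test between the peptides. Several genes near Gm9866 on chromosome 12 were higher with Cdk5i without passing the edgeR test over all genes. They included 2410018L13Rik (log2 fold change 2.00, adjusted p = 0.0843), Cdhr3 (1.72, adjusted p = 0.114), Dcdc2c (1.29, adjusted p = 0.114), the laminin gene Lamb1 (0.49, adjusted p = 0.114), the peroxidasin gene Pxdn (0.52, adjusted p = 0.116) and Eipr1 (0.37, adjusted p = 0.131), by edgeR. Prn, Lamr1-ps1 and Unc5c had log2 fold changes of -0.24, -0.24 and 0.12 between the peptides, with edgeR adjusted p values of 0.966, 0.966 and 0.945.

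**Figure D2:**
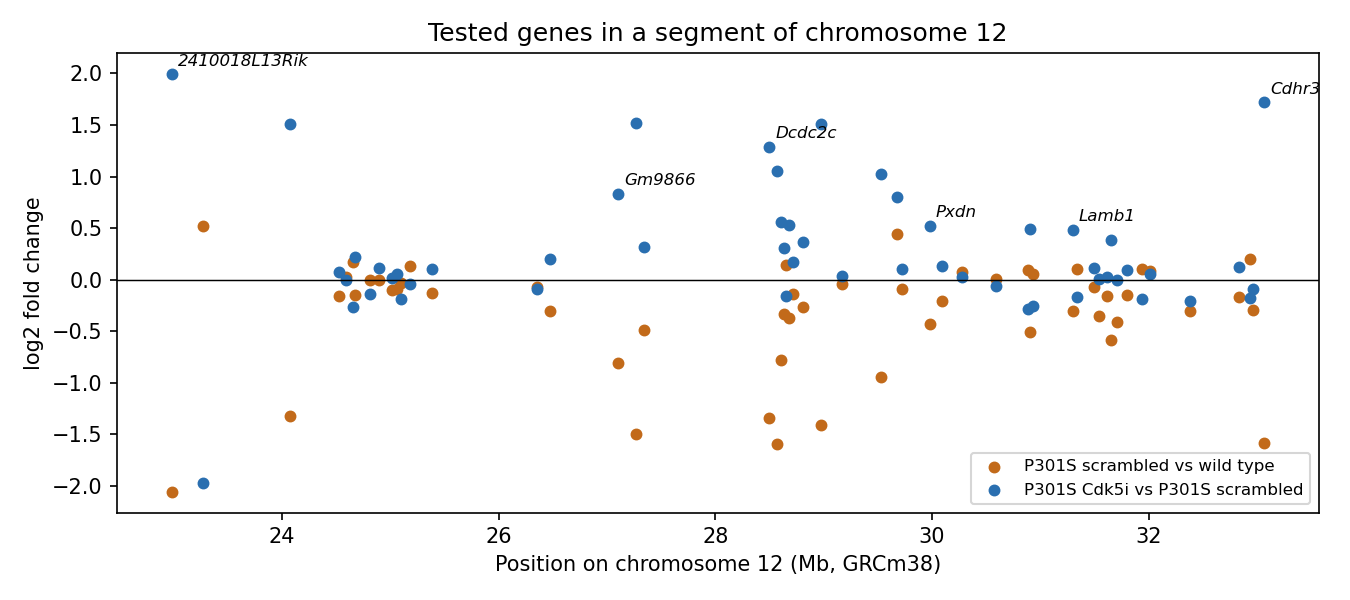
Log2 fold change (vertical axis) of 54 tested genes by position on chromosome 12 in Mb of GRCm38 (horizontal axis), for scrambled peptide against wild type and for Cdk5i against scrambled peptide, between 2410018L13Rik and Cdhr3, ends chosen after the data were seen. Of the 54 genes, 40 were below 0 in the first comparison, and the names mark 6 genes at their value in the second.

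Of the 34 gene lists, 11 changed between the peptides, 4 up and 7 down. Postsynaptic and glutamate receptor genes rose: 36 of 46 members were higher with Cdk5i, with a median log2 fold change of 0.11 (camera adjusted p = 1.10e-05, and adjusted p = 0.647 with an estimated correlation). The scaffold gene Dlg2 measured 5995 ± 587 CPM with Cdk5i and 5430 ± 432 CPM with scrambled peptide, and the adhesion gene Nlgn1 4076 ± 254 and 3778 ± 276 CPM (SD, n = 3). Voltage-gated ion channel genes rose by a median of 0.04 on the log2 scale, with 33 of 47 members higher (camera adjusted p = 0.0268, and 0.647 as adjusted p with an estimated correlation). Chromatin modifier and histone deacetylase genes rose by a median of 0.03, with 23 of 29 members higher (camera adjusted p = 0.0421, and 0.647 as adjusted p with an estimated correlation). Markers of striatal neurons, which lie next to the cortex, rose by a median of 0.19, with 12 of 14 members higher (camera adjusted p = 0.0421, and 0.841 as adjusted p with an estimated correlation). Among them, Meis2 measured 434 ± 135 CPM with Cdk5i and 304 ± 86.1 CPM with scrambled peptide, and Foxp1 446 ± 86.8 and 397 ± 51.3 CPM (SD, n = 3).

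Genes of energy metabolism and protein synthesis fell. Of 73 nuclear-encoded oxidative phosphorylation genes, 61 were lower with Cdk5i, with a median log2 fold change of -0.11 (camera adjusted p = 1.26e-05, and adjusted p = 0.647 with an estimated correlation). The cytochrome c oxidase gene Cox5b was lower when adjusted over the list alone, from 5.31 ± 0.435 to 3.12 ± 0.283 CPM (SD, n = 3), while Ndufs4 had a log2 fold change of -0.04. Of 76 cytosolic ribosomal protein genes, 61 were lower, with a median of -0.13 (camera adjusted p = 9.09e-04, and adjusted p = 0.711 with an estimated correlation), Rpl11 and Rpl3 having log2 fold changes of -0.12 and -0.10. All 9 measured mitochondrially encoded genes were lower, with a median of -0.21 (camera adjusted p = 0.00705, and adjusted p = 0.647 with an estimated correlation), including the mitochondrial ribosomal RNA genes mt-Rnr1 (-0.27) and mt-Rnr2 (-0.08).

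Heat shock protein genes fell by a median of 0.19 on the log2 scale, with 14 of 17 members lower (camera adjusted p = 0.0102, and adjusted p = 0.711 with an estimated correlation), among them the chaperone gene Hsp90ab1 (-0.40). Oligodendrocyte markers fell by a median of 0.26, with 11 of 14 members lower (camera adjusted p = 0.0136, and adjusted p = 0.647 with an estimated correlation), their sum being 198 ± 24.7 CPM with Cdk5i (SD, n = 3). Lipid and cholesterol synthesis genes fell by a median of 0.11, with 20 of 27 members lower, including Srebf2 (-0.20), the gene of a regulator of sterol synthesis. Autophagy and lysosome genes fell by a median of 0.07, with 24 of 36 members lower. The camera adjusted p was 0.00417 for the lipid list and 0.0201 for the autophagy list, and each had an adjusted p of 0.647 with an estimated correlation.

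**Figure D3:**
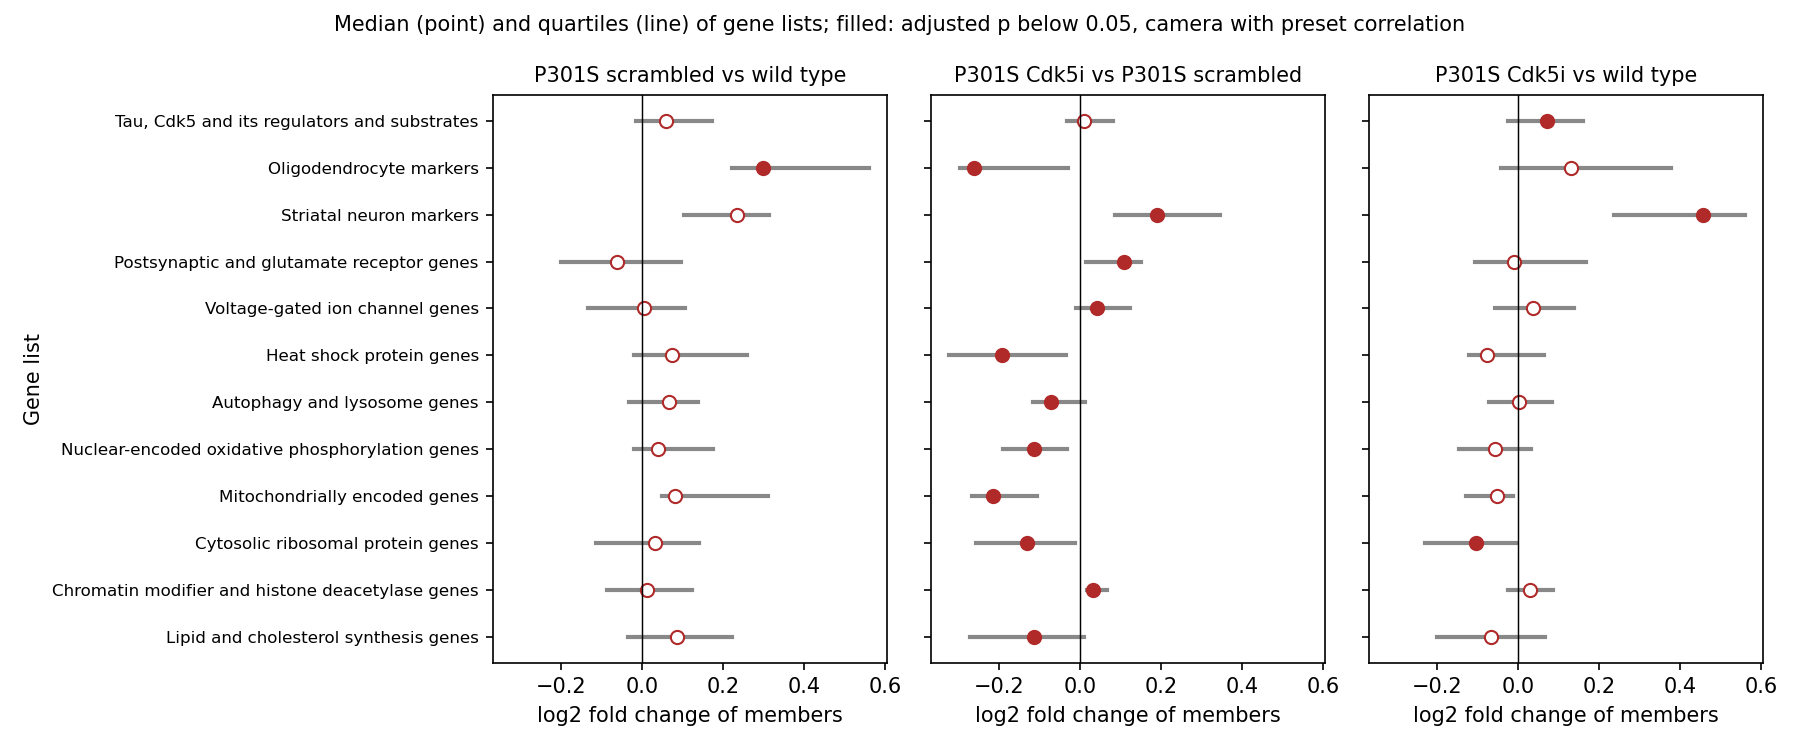
Log2 fold changes of the members of 12 gene lists (vertical axis) in the 3 comparisons (panels), with points for the median and lines for the quartiles. Filled points mark an adjusted p below 0.05 by camera with a preset correlation, 1, 11 and 3 lists in the order of the panels.

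When adjusted over the list alone, 1 inhibitory neuron marker, Adarb2, was higher with Cdk5i (log2 fold change 0.34), and the choroid plexus list held Enpp2 as lower (-0.29). In fry's test in 1 direction, which does not compare a list with other genes, antigen presentation and complement genes fell (fry adjusted p = 0.0381), and camera did not call them (adjusted p = 0.0754). The members lower over the list alone, Tap1, Tap2 and C4a, lie together on chromosome 17 between 34187553 and 34823464, and H2-D1 of the same region had 0 and 1 counts in scrambled replicates 2 and 3, against 28 to 67 in the other 7 libraries. The count of 11 lists fell to 1 when the score of mitochondrially encoded genes in each library was added to the fit, a choice made after the data were seen. The postsynaptic and oxidative phosphorylation lists passed with each of the 6 libraries left out in turn.

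Without Cdk5i replicate 1 the oligodendrocyte, postsynaptic and oxidative phosphorylation lists passed, 3 in all, and the other 8 of the 11 lists had camera adjusted p values of 0.0820 to 0.655. Without scrambled replicate 1 the count of lists was 5, with 7 of the 11 lists at 0.0547 to 0.961 by camera, and striatal markers, at the upper end of that range, turned to the opposite direction. Without scrambled replicate 2 it was 7, the ion channel, autophagy, mitochondrially encoded, ribosomal and chromatin lists having camera adjusted p values of 0.0841 to 0.578. The oligodendrocyte, ion channel and chromatin lists were lost without Cdk5i replicate 2 (camera adjusted p 0.148 to 0.511), the oligodendrocyte and striatal lists without Cdk5i replicate 3 (0.0828 and 0.461) and the heat shock list without scrambled replicate 3 (0.233). The striatal list was also lost with the score of inhibitory against excitatory markers in the fit (camera adjusted p = 0.262). Over the 15 alternatives the adjusted p ran from 1.23e-12 to 0.647 for the postsynaptic list and from 2.14e-06 to 0.647 for the oxidative phosphorylation list, and its highest value for the other 9 lists lay between 0.647 and 0.971.

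The third comparison asked what separated the Cdk5i-treated P301S mice from wild type. Of 12 genes past the threshold, 7 rose and 5 fell. Lamr1-ps1 was again read only in transgenic libraries among these 6, with 52 to 60 counts, at least 48.8-fold higher than wild type, and 4930590L14Rik had 14 to 20 counts, at least 14.7-fold higher. Mob3b rose 7.77-fold (log2 fold change 2.96, SE 0.20) and Prn 2.90-fold. The kainate receptor subunit gene Grik5 rose from 122 ± 9.80 to 167 ± 5.24 CPM (SD, n = 3), Pdzd2 rose 1.39-fold and 2610035D17Rik 1.35-fold. The edgeR adjusted p was 5.24e-04 for Lamr1-ps1, 5.99e-04 for Mob3b, 0.0238 for 4930590L14Rik, 0.0425 for Prn, 0.0450 for Grik5, 0.0415 for Pdzd2 and 0.0288 for 2610035D17Rik.

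Unc5c fell from 752 ± 45.3 to 525 ± 35.9 CPM (SD, n = 3), a log2 fold change of -0.52 with an edgeR adjusted p of 0.0288. The antisense RNA Gm27008 fell by 0.79 on the log2 scale, the cytoskeletal gene Gas2 by 0.42 and Ercc6l2, a helicase-like gene of DNA repair, by 0.36. Zfp990, a KRAB zinc finger gene whose near-identical copies can share reads, had 19 to 39 counts in wild type and 1 to 2 with Cdk5i, a log2 fold change of -4.34 with a standard error of 0.66. The edgeR adjusted p values of these 4 genes lay between 0.0288 and 0.0483. Mapt had a log2 fold change of 0.21 (edgeR adjusted p = 0.251), Cdk5 one of 0.07 (0.855) and Cdk5r1 one of -0.14 (0.548).

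Of the 34 lists, 3 changed. Striatal neuron markers rose by a median of 0.46 on the log2 scale, with 14 of 14 members higher, their sum moving from 1067 ± 289 CPM in wild type to 1500 ± 430 CPM with Cdk5i (SD, n = 3, camera adjusted p = 0.00288). Cytosolic ribosomal protein genes fell by a median of 0.10, with 59 of 76 members lower (camera adjusted p = 0.00622). The list of tau, Cdk5 and its regulators and substrates rose by a median of 0.07, with 20 of 32 members higher (camera adjusted p = 0.0280). None of the 3 calls held with an estimated correlation, each with an adjusted p of 0.967. None passed camera without wild-type replicate 1 (adjusted p 0.0799 to 0.230) or Cdk5i replicate 1 (0.0948 each). The tau and Cdk5 list was also lost without wild-type replicate 2 (camera adjusted p = 0.0592) and Cdk5i replicate 2 (0.171) and with the filter of 50 counts. The striatal list was lost with the score of inhibitory against excitatory markers in the fit (camera adjusted p = 0.110), and the count of lists was 5 without wild-type replicate 3 and 6 without Cdk5i replicate 3. Over the 15 alternatives the adjusted p ran from 0.00443 to 0.967 for the tau and Cdk5 list, from 5.83e-09 for striatal markers and from 3.95e-04 for ribosomal protein genes to the same highest value.

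When adjusted over the list alone, 5 genes of inhibitory synapses were lower than in wild type, among them Gphn (log2 fold change -0.48), Gabra2 (-0.36) and Gabra3 (-0.24). By the same measure Grik5 and the postsynaptic density gene Dlg4 (0.33) were higher, as were the calcium channel gene Cacna1h (0.40) and Ccnd3 (0.71), while Calb1 (-0.38) and Ddx3y (-0.24) were lower. Fry's test in 1 direction called antigen presentation and complement genes lower (fry adjusted p = 0.0214), which camera did not (adjusted p = 0.204).

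Before adjustment 1770 genes (11.0%) had p under 0.05, and 2608 (16.3%) had groups that did not overlap, against 10% by chance. Groups simulated without change gave at most 5 genes in 20 sets, with a lowest edgeR adjusted p of 4.04e-06, below the lowest here of 5.24e-04. Genes vary independently in these sets, which therefore lack any structure of the samples. Another split of the 6 libraries gave 46 genes. Lamr1-ps1 and Mob3b passed with each of the 6 libraries left out in turn. The count of 12 was 2 without wild-type replicate 3, 3 without Cdk5i replicate 1 and 4 without wild-type replicate 1, the other 10 genes having edgeR adjusted p values of 0.0797 to 0.273, 0.0596 to 0.174 and 0.0609 to 0.260. It was 5 without Cdk5i replicate 3, 6 without Cdk5i replicate 2 and 7 without wild-type replicate 2, where 4 of the 12 passed each time and the other 8 had edgeR adjusted p values of 0.0512 to 0.0877, 0.0641 to 0.141 and 0.0622 to 0.0792. DESeq2 called 115 genes, 8 of them among the 12, while the count was 2 with only the groups compared or with the mitochondrial score in the fit, 3 with non-robust dispersion and 6 with a filter of 50 counts, each of these genes being among the 12.

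The last comparison asked whether Cdk5i moved the genes of the P301S difference back. Gm9866 was the single gene past the threshold with opposite signs in the first and second comparisons, against 8.72e-04 for independent lists and at most 1 gene in sets simulated without change that share the scrambled-peptide libraries. Of the 13 genes of the first comparison, 11 had the opposite sign between the peptides and 11 had a smaller difference from wild type with Cdk5i. In sets simulated without change, the 13 genes of lowest p gave a mean of 12 for each count (9 to 13), so neither exceeded what the shared libraries give. Of the 13 genes, 6 still differed from wild type with Cdk5i: Lamr1-ps1, 4930590L14Rik, Prn, Pdzd2, 2610035D17Rik and Unc5c. Lamr1-ps1 and Prn lie next to each other on chromosome 2, and 4930590L14Rik and Unc5c lie near each other on chromosome 3. The 6 genes are thus not independent positions, and why these neighbours differ together was not tested. The first and second comparisons share the scrambled-peptide libraries with opposite signs, which alone makes their fold changes run against each other. Across 16046 genes, which are not independent replicates, Pearson's r was -0.43, against a mean of -0.50 in groups simulated without change. The covariance was -0.0344 against a simulated mean of -0.0337 (range -0.0364 to -0.0312), a difference of -6.77e-04.

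When the scrambled-peptide libraries were divided between the contrasts, 1 against 2, r averaged -0.017 over 6 divisions. The number of genes past both thresholds was 12 without scrambled replicate 3, 4 without scrambled replicate 1 and 2 without Cdk5i replicate 1 or 3. Both comparisons with wild type share the wild-type libraries. Of the 6 genes in both, 5 rose and 1 fell, against 0.00262 and 0.00218 for independent lists, a figure that leaves out the shared libraries. Sets simulated without change held at most 2 such genes, but they called at most 3 genes in the first comparison and 5 in the third. They could therefore not hold 6, and their count does not bear on the overlap. Pearson's r across genes was 0.61 against a simulated mean of 0.51. The covariance of the fold changes was 0.0549 against a simulated mean of 0.0350 (range 0.0323 to 0.0369), a difference of 0.0200. When the wild-type libraries were divided between the contrasts, 1 against 2, a choice made after the data were seen, r averaged 0.16 and the covariance 0.0165 over 6 divisions (covariance 0.00476 to 0.0224).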

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

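The covariates, the list tests with other scalings and the division of the wild-type libraries were chosen after seeing the data, the other alternatives before. Of 1753 values recomputed for 93 results on single genes, 1468 kept their direction and side of the threshold, 196 lost the threshold, 72 gained it and 17 changed sign, and of 225 for 15 gene list results 144, 79, 0 and 2 did. Mob3b and Gm9866 passed between the peptides in 19 of 19 alternatives, and Lamr1-ps1 against wild type in 19 of 19 with scrambled peptide and 18 of 18 with Cdk5i. In data simulated at this depth, 32.4, 38 and 40% of genes changed by 0.5 on the log2 scale were recovered for scrambled peptide against wild type, Cdk5i against scrambled peptide and Cdk5i against wild type. The cause of a changed value was not tested unless stated.

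For scrambled peptide against wild type, Cdk5i against scrambled peptide and Cdk5i against wild type in turn, the counts of 13, 2 and 12 genes were 75, 26 and 115 with DESeq2 and 318, 159 and 408 with no low-count filter, 309, 153 and 397 of these among the 16046 genes. A filter of 50 counts left 6 genes in each comparison with wild type, fewer genes being tested. With non-robust dispersion these comparisons gave 6 and 3 genes. With only the groups compared, Cdk5i against wild type gave 2 genes. With 1 surrogate variable the comparison of the peptides gave 18 genes. The inhibitory score gave 7 between the peptides and 19 for Cdk5i against wild type, the immediate early gene score 4 between the peptides, and the mitochondrial score 3 and 2 against wild type. Leaving out single libraries gave 2 to 17, 2 to 18 and 2 to 7 genes.

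Replicate numbers did not pair the libraries: same-numbered libraries had correlations of their deviations from -0.31 to 0.17, and 1 library correlated best with its own number. With the replicate block each comparison gave 2 genes, and the list counts were 1, 11 and 3.

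The list counts of 1, 11 and 3 were 0 in each comparison with camera and an estimated correlation, also at an unadjusted p under 0.05, and 0, 1 and 1 with fry. With the mitochondrial score they were 2 for scrambled peptide against wild type and 1 between the peptides. Leaving out single libraries gave 1 to 7, 3 to 12 and 0 to 6 lists. Striatal markers between the peptides turned to the opposite direction with the mitochondrial score (camera adjusted p = 0.970) and without scrambled replicate 1, the camera adjusted p being 1.90e-06 to 0.961 over the single libraries left out.

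The count of 1 reversed gene was 1 to 12 and the correlation -0.57 to -0.34 when single libraries were left out. The correlation was -0.41 with the filter of 50 counts and -0.017 with separate scrambled libraries, which removes the shared libraries by construction. Between the comparisons with wild type, the correlation of 0.61 was 0.64 with the filter of 50 counts, 0.50 to 0.72 when single libraries were left out and 0.16 with separate wild-type libraries, for the same reason.

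Genes that changed sign passed no threshold. Between the peptides, the mitochondrial score gave log2 fold changes of 0.22 for Rpl11, 0.041 for Rpl3, 0.25 for mt-Rnr2 and -0.058 for Foxp1. Leaving out single libraries gave -0.34 to 0.091 for Rpl11, -0.20 to 0.12 for Rpl3, -0.26 to 0.11 for mt-Rnr2, -9.99e-04 to 0.28 for Foxp1 and -0.091 to 0.021 for Ndufs4. Cdk5r1 with scrambled peptide against wild type had 0.0087 with 1 surrogate variable, 0.0067 with the inhibitory score and -0.029 to 0.015 over the single libraries left out, and Cdk5 with Cdk5i against wild type -0.015 to 0.15.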

Other observations

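The tests of the neighbours of Mob3b and of single libraries, of the chromosome 12 segment and of segments elsewhere, of the score covariates and of other splits of the libraries were chosen after the results they bear on were seen.

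Immediate early genes, which neurons switch on with activity, varied between libraries of each group more than between groups. Arc ranged from 10.9 to 38.7 CPM in wild type, from 15.7 to 41.2 CPM with scrambled peptide and from 6.25 to 43.5 CPM with Cdk5i, and Fos from 0.580 to 5.36 CPM over the 9 libraries. The list of 31 measured members did not pass camera in any comparison (adjusted p = 0.839, 0.215 and 0.638 in the order of the report). Its median log2 fold change was 0.12, -0.17 and 0.01.

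Several antigen presentation and complement genes of a single region had lower values with Cdk5i. The peptide transporter genes Tap1 (log2 fold change -1.29, 4 to 8 counts with Cdk5i against 15 to 19) and Tap2 (-0.80) and the complement gene C4a (-0.79) were lower with Cdk5i than with scrambled peptide when adjusted over the list alone, and all 3 lie in the major histocompatibility complex on chromosome 17, between 34187553 and 34823464. Tnxb, in the same complex, had a log2 fold change of -0.84, and the class I gene H2-D1 (35262730 to 35267499) one of 2.27. H2-D1 had 0 and 1 counts in scrambled replicates 2 and 3 and 28 to 67 in the other 7 libraries. Reads of C4a and H2-D1 are uncertain, since both have near-identical relatives that can share reads. H2-D1 differed within the scrambled-peptide group, whose replicate 1 is among the 7 libraries with 28 to 67 counts, and the peptide does not account for that difference. Whether Tap1, Tap2, C4a and Tnxb differ through the peptide or through an inherited difference of the region between the mice was not tested, and both stay open. By edgeR over all genes the adjusted p was 0.768 for Tap1, 0.671 for Tap2, 0.871 for C4a, 0.128 for Tnxb and 0.922 for H2-D1. Besides Lamr1-ps1 and 4930590L14Rik, the transcript AC140413.3 on chromosome 19 had 0 counts in wild type and at least 3 in each transgenic library, at least 3.45-fold and 4.75-fold higher, and it was too low to be tested.

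Mob3b was higher in the Cdk5i libraries. One library alone is argued against, since 3 of 3 Cdk5i libraries lay above the other 6. A gained copy of the region is argued against as well: the 10 tested genes within 1 Mb had a median log2 fold change of 0.066 (range -0.04 to 0.58), although its neighbour C9orf72 had 0.32 and a gain of Mob3b alone is not covered. Large-effect variants that segregate among mice without regard to group stay open, because 1 of 81 trios of libraries from mixed groups had a gene set apart from the other 6 libraries by 3-fold, against 1 such gene for the Cdk5i trio, too few to decide. The trios cover only divisions of 3 against 6 libraries, among 11916 genes with a mean count of at least 50. A variant carried by another number of mice would be missed. Nor do the trios test a variant at Mob3b that the Cdk5i libraries alone share. An effect of the peptide stays open as a hypothesis, untested beyond the comparison itself.

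Several genes between 22953997 and 33092875 on chromosome 12, among them Gm9866, Dcdc2c and 2410018L13Rik, had their lowest levels with scrambled peptide. The ends were set after the data were seen, at 2410018L13Rik and Cdhr3, and of the 54 genes tested there 40 had negative fold changes against wild type, while Gm20472 went the other way (0.52 against wild type and -1.97 between the peptides). Loss of a copy of the segment is argued against, since its 54 genes had a median log2 fold change of -0.15 against wild type and a lower quartile of -0.43. Chromosome segments that differ between the mice of the groups may contribute and stay open: off chromosome 12, the 50 genes of lowest p held 17 pairs within 5 Mb between the peptides and 19 for Cdk5i against wild type (34 and 6 of 10000 random sets held as many, with a mean of 6.65), but 7 for scrambled peptide against wild type (4759 of 10000). With chromosome 12 these counts were 36, 19 and 16, against at most 27, 15 and 18 in other splits, and a change of these genes by the peptide was not tested separately. Random sets with chromosome 12 had a mean of 6.36 pairs, below these highest other splits. The shares of random sets may therefore be too small. Pairs off chromosome 12 were not counted in other splits, so these shares do not decide for inherited segments.

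The lists of metabolic and synaptic genes shifted by small amounts between the peptides. Of 10000 random lists matched on gene length and expression level, 0.1% had a median as far out for the oxidative phosphorylation list, 0% for the postsynaptic list and 5.66% for the ribosomal list, which may follow length and level. For the oxidative phosphorylation and postsynaptic lists the matched lists had medians of -0.06 and 0.04, against -0.11 and 0.11, so length and level alone gave smaller shifts. Random genes need not vary together as members of a list can, so these shares may be too small. They cannot decide whether the rest of the shift exceeds shared variation of the samples. The share of inhibitory nuclei is argued against as the whole cause for 10 of the 11 lists, which passed among 11 lists with its score in the fit (their medians moving at most from -0.19 to -0.15, for heat shock genes), but stays open for striatal markers, which were lost (camera adjusted p = 0.262, and 1.90e-06 to 0.970 over the alternatives) as their median moved from 0.19 to 0.13. Mitochondrial and cytoplasmic RNA carried along with the nuclei may account for part of the shift: with the mitochondrial score in the fit 1 list passed, that of oligodendrocyte markers, though the score was built from 1 of the 11 lists and differs between the groups. With this score the median log2 fold change moved from -0.11 (quartiles -0.19 to -0.03) to -0.05 (quartiles -0.14 to 0.02) for oxidative phosphorylation, from -0.13 (quartiles -0.26 to -0.01) to 0.02 (quartiles -0.12 to 0.13) for ribosomal, from 0.11 to 0.05 for postsynaptic, from 0.19 to -0.0017 for striatal, from -0.21 to -0.04 for mitochondrially encoded, from -0.07 to -0.02 for autophagy, from 0.04 to 0.02 for ion channel, from -0.11 to -0.07 for lipid, from -0.26 to -0.19 for oligodendrocyte, from -0.19 to -0.13 for heat shock and from 0.03 to 0.02 for chromatin genes, and why the calls of the lists that shrank least ended was not tested.

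Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Scrambled peptide against wild type gave 13 genes, against at most 1 in another split, the real split being the 1 with as many. Cdk5i against scrambled peptide gave 2 genes and the highest other split 76, so that 2 splits had as many. That split put scrambled replicates 1 and 2 with Cdk5i replicate 3, and points to a structure of the samples. The same 3 libraries had the highest values on the second principal component among the 6 (14.6, 27.4 and 16.9), which is computed from the same values and is no independent check. Cdk5i against wild type gave 12 genes and the highest other split 46, with 2 splits reaching 12. That split joined wild-type replicates 1 and 3 with Cdk5i replicate 2 and points to a structure of the samples as well. For lists, the real and the highest other counts were 1 and 9 in the first comparison, 11 and 12 in the second and 3 and 13 in the third, with 10, 3 and 9 splits of 10 reaching the real count.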
